A study of Mus musculus with 2 samples.

How the data were processed

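RNA of single cells was measured in 2 libraries of the aging mouse ovary, replicates 1 and 2 of the same group per the labels. Per the labels' protocols, cells were released by enzymatic digestion and libraries were made with the 10x 3' v3 kit. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 6.0.1 and mm10 per the submitters' processing notes, for every barcode before cells were called. The files hold 32286 features (32246 gene symbols, features of the same symbol summed) and 1405493 and 2005206 barcodes. Coordinates come from a GENCODE annotation of the same build, matched on the gene identifiers. The features end with EGFP, a sequence added to the reference. The libraries share 4 of their barcodes among the cells kept.

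A barcode was taken as a cell with at least 1000 UMIs, at least 500 genes and at most 25% of UMIs from mitochondrially encoded genes. In libraries 1 and 2, 1689 and 4729 barcodes passed the minimum of UMIs and genes, and 1654 and 4687 also the mitochondrial limit. Scrublet (in scanpy 1.11.5, run per library) called 5 of these 6341 barcodes doublets, 0.079%, so it did not work here at its automatic threshold. Doublets therefore remain among the 6336 cells kept, and an alternative removed the 6% of cells with the highest score. The cells hold 83.06% and 94.91% of all UMIs. At a median of 15135 and 16619.5 UMIs per cell, the precision of a class value is set by the number of cells, which in library 1 was 47 for luteal and 88 for stromal fibroblast cells.

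Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, ranked within each library and without any gene of the tested lists, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1 over both libraries without batch correction (anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, Python 3.11.15). The 23 clusters were named from marker lists. A marker counted as detected in a cluster with a UMI in at least 10% of its cells and at least 20% of its highest level over clusters. That highest level was taken as no less than 20 CPM. A name needed 3 detected markers. Clusters stayed unnamed where the leading genes went against the name, where they were shallow (a median UMI count under 0.3333 of their library's) with none of the name's markers among the 10 leading genes, or where the median doublet score was over 0.2. The markers, lists, tests and the rule for named genes were set before the data were examined. The scoring rule for names was revised after clusters had been seen and before any test between classes, and the doublet limit was set then too. Clusters kept out of a class by these rules hold 581 cells of library 1 and 299 of library 2. The stromal fibroblast cluster also had Acta2 and Tagln of smooth muscle among its 10 leading genes, and the T cell cluster was led by Trdc, Icos, Cd163l1 and Il7r.

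A class was tested with at least 30 cells in each library, which left granulosa, luteal, stromal fibroblast and surface epithelial cells. Raw counts were summed per library and class and fitted in one model by edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and the library as a covariate, and each class was contrasted with the unweighted mean of the other 3 by the quasi-likelihood test, with Benjamini-Hochberg adjustment over 14205 genes. The class contrasts of a gene are not independent, since each class is part of the mean that the others are set against. The fit has 3 residual degrees of freedom, which come from classes that behave differently in the libraries. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over all lists and classes, and again with an estimated correlation. With the estimated correlation no list passed in the main fit, where camera's smallest unadjusted p was 0.0452. Most lists then share a tied adjusted p of 0.759, which does not tell them apart. Each SE is the absolute log2 difference divided by the square root of the quasi-likelihood F statistic. It rests on the spread of the whole fit and is not a standard error over the libraries' own values. Class CPM values are TMM-scaled unless called unscaled. For Hif1a-detected against undetected cells each cell was thinned to 2000 UMIs, cells of each library and class with and without a Hif1a UMI were drawn in equal number, counts were summed, and Hif1a was left out. Thinning and the draw of cells were made once per setting, with fixed seeds. The fit has 4 sums and 1 residual degree of freedom. The same was done with 100 other splitting genes of the closest share of cells with a UMI. Class shares have exact Clopper-Pearson 95% intervals and counts, where an interval is given, exact Poisson 95% intervals, for counting error only. A count of 0 was set to a floor of 3 counts over the class. Granulosa clusters were compared in the same way as classes, each with the mean of the others, after the data had been seen. The cluster found almost wholly in library 1 has no replicate, so its lists are given as percentiles among 10000 random lists matched on mean expression, with no test. The log2 ratios and the 2-fold counts of those lists have 5 CPM added to each level, and single-gene ratios have none.

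Named genes were a fixed set of HIF and glycolysis genes, and for each other list, in the class of its smallest camera p, up to 2 higher and 2 lower called members with the largest difference and the same sign in both libraries. For the split up to 10 genes each way were named by the same rule, and between libraries up to 10 each way that were at least 3-fold apart in the most classes. Some genes that met these rules are not reported here. On simulated counts the class test recovered 91% of genes changed 2-fold and 100% of those changed 4-fold, with 8 false calls among 13309 genes. The split test recovered 71% at 1.5-fold and 100% at 2-fold, with 9 false calls among 10268 genes. Changed genes were drawn only from those above a minimum count. The simulated counts held no other class difference, no library effect besides total counts, and a common dispersion for all genes (0.0175 and 0.002). These rates need not hold for the real counts.

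Alternatives set before the data were examined were other minimums of UMIs, cell calling by UMI rank, other mitochondrial limits, Scrublet calls kept, other clustering resolutions, each library clustered by itself, list genes allowed in clustering, size factors of DESeq2 1.42.0 or library size in place of TMM, DESeq2's Wald test or fry, no low-count filter, no library block, free RNA subtracted, equal cell numbers per class (47 drawn from each), other thinning depths, no matching by class and each library by itself. Alternatives added after the data had been seen were 9 classes of at least 10 cells, removal of the 6% of cells with the highest doublet score, matching by cluster, and a luteal class that includes the unnamed cluster of library 1. Free RNA was taken from barcodes with at most 50 UMIs. Reads shared by near-identical genes were not resolved, and the libraries were not contrasted, since the labels give no difference between them.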

Results

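Gene expression was measured in single cells of the aging mouse ovary, released by enzymatic digestion and captured in droplets with 10x 3' v3 chemistry, in which every captured RNA molecule carries a unique molecular identifier (UMI). The series holds 2 libraries, replicates 1 and 2 of the same group, and its title names HIF1A, glycolysis and the metabolic plasticity of the ovarian microenvironment. Library 1 held 34415635 UMIs and gave 1650 cells with a median of 15135 UMIs and 3892 genes per cell. Library 2 held 105261679 UMIs and gave 4686 cells with a median of 16619.5 UMIs and 4129 genes. The labels give no age, treatment or animal for either library, so values of the libraries stand side by side and the comparisons run between cell types within them. The 2 libraries may be technical replicates, and p-values then measure only the spread between them.

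The ovaries yielded mainly granulosa-like cells, the hormone-producing cells that surround the oocyte in the follicle. They made up 43.8% of the cells of library 1 (exact binomial 95% interval 41.4 to 46.3) and 51.9% of library 2 (50.5 to 53.4). Surface epithelial-like cells, which cover the ovary, made up 7.64% (6.40 to 9.03) and 22.4% (21.2 to 23.6). Stromal fibroblast-like cells made up 5.33% (4.30 to 6.53) and 6.55% (5.86 to 7.30), and luteal-like cells, the steroid-producing cells of the corpus luteum, 2.85% (2.10 to 3.77) and 5.04% (4.43 to 5.70). Smaller classes were theca-like cells at 1.70% and 2.39%, blood endothelial-like cells at 1.21% and 2.03%, T cell-like cells at 0.970% and 1.45%, NK cell-like cells at 0.667% and 1.22%, and macrophage- or monocyte-like cells at 0.606% and 0.640%. No cluster carried the oocyte name. Cells in clusters that stayed unnamed made up 35.2% of library 1 (581 cells) and 6.38% of library 2 (299 cells), which lowers every named share of library 1. Of those 581 cells, 293 belonged to a single cluster found almost wholly in library 1, against 47 in its luteal class. That cluster had 8 of 10 luteal markers detected. It stayed unnamed because the theca marker Mgarp, and no luteal marker, was among its 10 leading genes. The luteal share of library 1 therefore depends strongly on this rule. The intervals cover counting error only, and no test was made between the libraries.

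**Figure D1:**
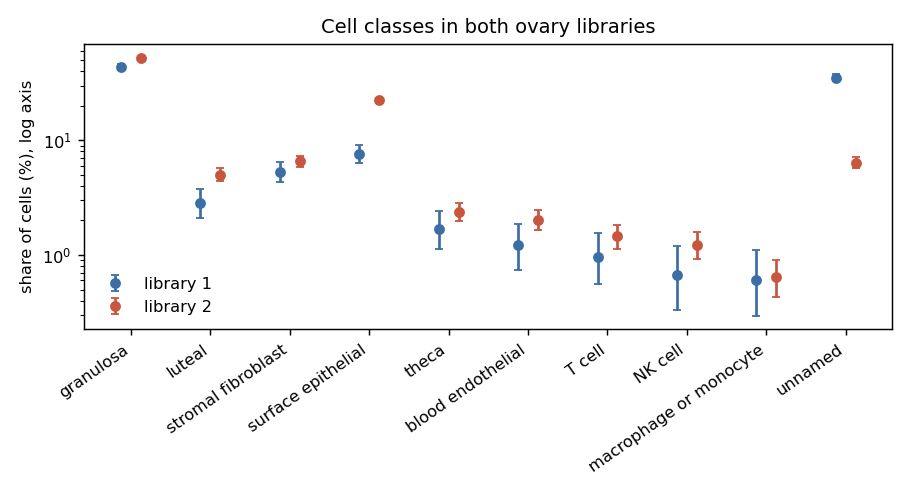
Share of cells (percent, log axis) in each class, as points for library 1 and library 2 with bars for exact binomial 95% intervals. Granulosa-like cells were the largest class in both libraries, at 43.8% and 51.9%, and unnamed clusters held 35.2% and 6.38%.

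Hif1a, the gene of the oxygen-regulated subunit of hypoxia-inducible factor 1, was highest in granulosa cells among the 4 classes with enough cells in both libraries to be tested. Its level there was 257 CPM (TMM-scaled) in library 1 and 284 in library 2, against 196 and 200 in luteal cells, 127 and 150 in stromal fibroblasts and 124 and 134 in surface epithelial cells. Each class was compared with the unweighted mean of the other 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14205 genes. Granulosa cells were higher by 0.83 on the log2 scale (SE 0.116 from the fit over all class sums, n = 2 libraries, adjusted p = 5.87e-05), and the single libraries gave 0.82 and 0.84. Surface epithelial cells were lower, at −0.60 (SE 0.130, adjusted p = 0.00150), as were stromal fibroblasts, at −0.46 (SE 0.131, adjusted p = 0.0158), with negative values in both libraries. Luteal cells gave 0.22 (SE 0.123, adjusted p = 0.158). The gene, ENSMUSG00000021109, lies on chromosome 12 from 73901375 to 73947530 in mm10.

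With every cell thinned to 2000 UMIs, a Hif1a UMI was seen in 38.3% of granulosa cells of library 1 and 42.4% of library 2, in 34.0% and 34.8% of luteal cells, in 25.9% and 19.8% of stromal fibroblasts and in 18.7% and 22.7% of surface epithelial cells. No ovarian type is known to lack Hif1a. The lowest shares were those of the macrophage- or monocyte-like cells, 14.3% of 7 cells and 17.2% of 29 cells, and free RNA in near-empty droplets held Hif1a at 151 CPM in both libraries. By the markers of other types, free RNA was estimated at no more than 9.50% of the UMIs in any tested class and library, the lowest estimate being 4.0%. Over all named cells, 34.4% and 34.5% had a Hif1a UMI after thinning, which left out 61 shallower cells, and 83.4% and 83.3% before it. The call in stromal fibroblasts was lost when libraries were not entered in the model (adjusted p = 0.0661), with equal cell numbers per class (0.0595), with the library 1 cluster counted as luteal (0.0598) and with 9 classes, which adds those of at least 10 cells (0.147), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (range over all alternatives 0.00125 to 0.147). That in surface epithelial cells was lost with equal cell numbers (0.115) and with 9 classes (0.0560, range 2.77e-07 to 0.115), while the granulosa call held in every alternative that gave a test. With 9 classes the median of all genes rose to 0.34 in granulosa, 0.33 in luteal, 0.26 in stromal and 0.29 in surface epithelial cells, from −0.01, −0.04, −0.06 and −0.02, so values of that fit carry a shift shared by most genes.

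**Figure D2:**
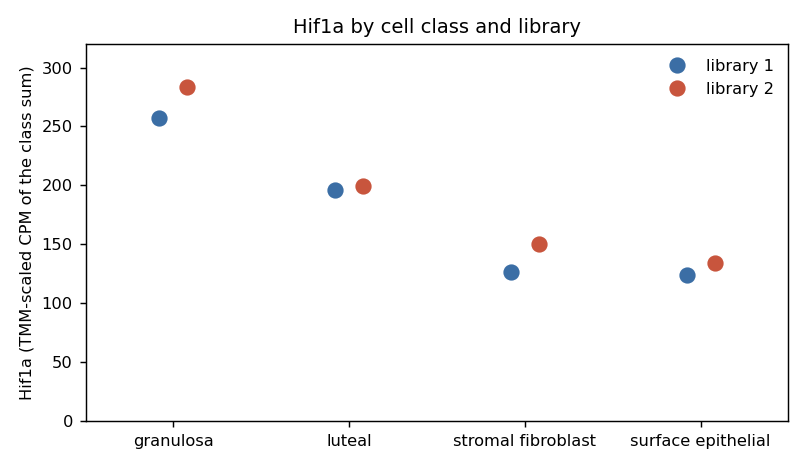
Hif1a level (TMM-scaled CPM, vertical axis) in each tested class (horizontal axis), with 1 point per library and no intervals drawn. Granulosa cells stood at 257 and 284 CPM, surface epithelial cells at 124 and 134.

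The other genes of the HIF pathway set the classes apart in different ways. Epas1, which encodes HIF-2 alpha, was higher in granulosa cells by 1.54 (SE 0.123, adjusted p = 4.22e-07) and lower in surface epithelial cells, at −2.08 (SE 0.166, adjusted p = 1.75e-07). Egln3, a prolyl hydroxylase that marks HIF alpha for destruction, was higher in surface epithelial cells by 3.88 (SE 0.231, adjusted p = 8.18e-09), with 19.9 and 26.8 CPM there against 0.195 and 0.623 CPM in granulosa cells. Egln2, a related hydroxylase, was highest in luteal cells (1.12, SE 0.129, adjusted p = 1.33e-05) at 86.8 and 81.2 CPM. Arnt, the constant partner of HIF alpha, was lower in luteal cells (−0.83, SE 0.164, adjusted p = 0.00112). Vhl, which recognises hydroxylated HIF alpha, and Hif1an, which hydroxylates its transactivation domain, passed the test in none of the 4 classes, with values from −0.30 to 0.46 and from −0.34 to 0.36. Hif3a had too few counts to be tested.

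Many genes were called in every class. Of all 14205 genes, 3493 were higher and 3516 lower in granulosa cells, and 3207 and 2905 in luteal cells. Stromal fibroblasts had 2614 and 2197, and surface epithelial cells 4047 and 3817. Counts of called list members, here and below, are to be read against these. As a list, the 16 measured HIF pathway genes were called in no class by camera, which compares a list with all other genes. In granulosa cells 3 were higher and 3 lower (3 and 3 adjusted over the list alone), with a median of 0.07 and a mean of −0.05. Luteal cells had 6 higher and 1 lower (6 and 1 adjusted over the list alone), and surface epithelial cells 4 higher and 7 lower (4 and 7 adjusted over the list alone). The 27 HIF targets outside glycolysis were not called in any class either. Of these, stromal fibroblasts had 4 higher and 11 lower (5 and 11 adjusted over the list alone), with a median of −0.37 and a mean of 0.01. Ndufa4l2, which replaces a subunit of respiratory complex IV, was higher there by 6.55 (SE 0.317, adjusted p = 2.24e-09; 4.22 to 8.25 over the alternatives) and Lox, which crosslinks collagen, by 4.26 (SE 0.239, adjusted p = 9.86e-09). The cluster of this class also had 6 of 8 smooth muscle markers detected, and resolution 2 gave a pericyte class of 9 and 25 cells. Such cells may share in these values. Tfrc, the transferrin receptor, was lower in stromal fibroblasts by edgeR's quasi-likelihood test (−1.83, SE 0.194, Benjamini-Hochberg adjusted p = 6.48e-06). Edn1, the gene of endothelin 1, was also lower at −3.03 (SE 0.521, adjusted p = 4.80e-04), but stood at 0.30, near the median of all genes, when endothelial and other small classes joined the comparison. In granulosa cells the targets had a median of 0.18 and a mean of −0.09.

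Glycolytic enzymes took a larger share of the UMIs of granulosa and luteal cells than of the other tested classes. The list held 0.508% of granulosa UMIs in library 1 and 0.476% in library 2, and 0.506% and 0.460% of luteal UMIs, against 0.326% and 0.323% in surface epithelial cells and 0.264% and 0.307% in stromal fibroblasts. In granulosa cells 11 of the 21 measured genes were higher and 5 lower (12 and 5 adjusted over the list alone), with a median of 0.41. Luteal cells had 10 higher and 3 lower (11 and 3 adjusted over the list alone), with a median of 0.53, which was 0.64 in library 1 and 0.24 in library 2. In stromal fibroblasts 4 were higher and 11 lower (4 and 12 adjusted over the list alone), median −0.51, and in surface epithelial cells 3 were higher and 11 lower (3 and 11 adjusted over the list alone), median −0.40. Tested against all other genes by camera, the list was called in no class, with Benjamini-Hochberg adjusted p = 0.0805, 0.0666, 0.0898 and 0.118 in granulosa, luteal, stromal and surface epithelial cells. It passed in granulosa cells (adjusted p = 0.0376, range over all alternatives 0.0376 to 0.759), luteal cells (0.0376, range 0.0119 to 0.759) and stromal fibroblasts (0.0441, range 0.0441 to 0.759) when the 6% of cells with the highest doublet score were removed, a step chosen after the data had been seen, and in the last pair also without a low-count filter. With an estimated correlation it passed in none of these (adjusted p of 0.565 or more).

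Single enzymes separated the classes more clearly than the list did. Ldha, the lactate dehydrogenase subunit that favours lactate production, was higher in granulosa cells by 1.19 (SE 0.138, adjusted p = 1.11e-05) and lower in surface epithelial cells, at −1.70 (SE 0.166, adjusted p = 1.34e-06). Ldhb, the subunit that favours pyruvate, ran the other way in surface epithelial cells, higher by 1.38 (SE 0.144, adjusted p = 2.41e-06). Its luteal value of −1.40 (SE 0.169, adjusted p = 2.04e-05) turned to 0.50 with 9 classes. Eno1 (1.42, SE 0.135, adjusted p = 1.85e-06) and Pgk1 (1.002, SE 0.148, adjusted p = 8.99e-05) were also higher in granulosa cells, and Aldoa was higher in luteal cells (0.97, SE 0.120, adjusted p = 2.53e-05) and lower in stromal fibroblasts (−1.17, SE 0.138, adjusted p = 1.75e-05). Hk2, an inducible hexokinase, was higher in stromal fibroblasts by 1.16 (SE 0.235, adjusted p = 0.00168) and lower in granulosa cells (−1.02, SE 0.246, adjusted p = 0.00386). Its granulosa call was lost with 9 classes, and its luteal value of 0.77 rested on library 1, with 194 CPM there against 61.9 in library 2. Pfkp, the platelet-type phosphofructokinase, was higher in granulosa (1.004) and luteal cells (0.71) and lower in surface epithelial cells (−1.47, SE 0.168, adjusted p = 6.38e-06), but the values in granulosa and luteal cells turned to −0.11 and −0.45 with 9 classes. Gapdh, Pkm, Eno1, Pgk1, Ldha and Aldoa have processed pseudogenes or a second gene entry that can take part of their reads, so their levels are uncertain. All single-gene p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

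**Figure D3:**
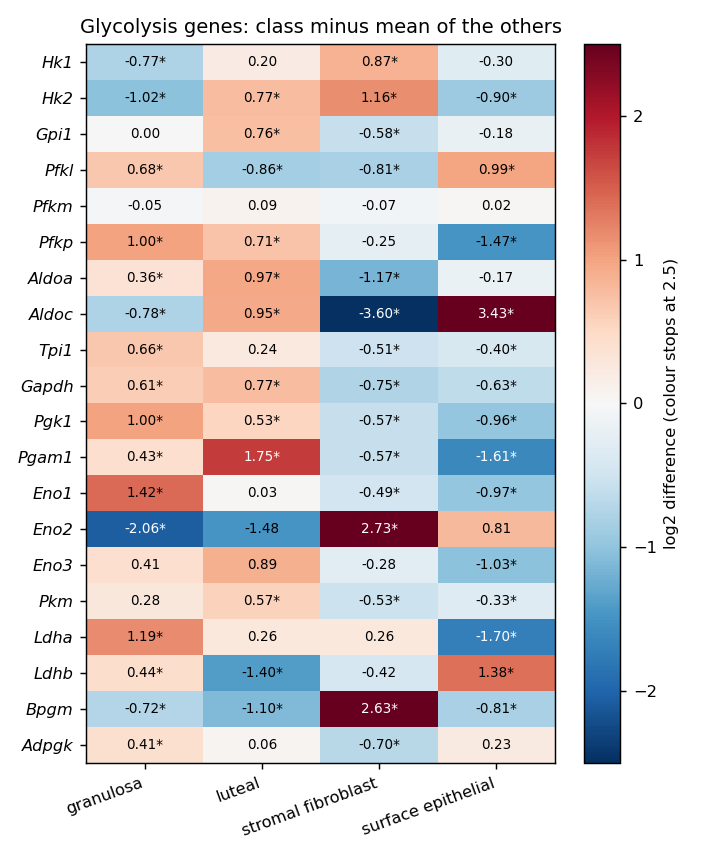
Log2 difference of 20 of the 21 measured glycolysis genes (rows) in each tested class (columns) against the mean of the other classes, with colour that stops at 2.5 and an asterisk for an edgeR adjusted p under 0.05. Ldha stood at 1.19 in granulosa and −1.70 in surface epithelial cells.

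Genes that move glucose and lactate or set the flux through glycolysis were led by surface epithelial cells. Of 17 measured, 9 were higher there and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.67 and a camera adjusted p of 0.0805. Bsg, the chaperone of the lactate carriers, was higher by 1.61 (SE 0.123, adjusted p = 1.07e-07), Slc16a1, the lactate carrier MCT1, by 1.24 (SE 0.131, adjusted p = 2.97e-06), and Pdk2, which restrains pyruvate dehydrogenase, by 1.89 (SE 0.196, adjusted p = 2.34e-06). The glucose carrier Slc2a1 was higher by 0.48 (SE 0.143, adjusted p = 0.0122) and Pdk1 by 0.67 (SE 0.192, adjusted p = 0.00930). Luteal cells had higher Pfkfb3, which makes an activator of phosphofructokinase (1.59, SE 0.213, adjusted p = 5.04e-05), and lower Slc16a3, the lactate exporter MCT4 (−2.11, SE 0.330, adjusted p = 1.86e-04). Slc16a3 in granulosa cells stood at 0.63 and turned to −0.86 with equal cell numbers per class, which also ended its luteal call, and the calls of Slc2a1 and Pdk1 were lost with 9 classes. These are edgeR quasi-likelihood values with Benjamini-Hochberg adjustment.

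Nuclear genes of oxidative phosphorylation, fatty acid oxidation and the TCA cycle, and genes of the pentose phosphate pathway, were higher in luteal cells. Of 78 nuclear genes of oxidative phosphorylation, 66 were higher and 1 lower (69 and 1 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 5.33e-14; adjusted p = 0.759 with an estimated correlation). Ndufc1 of complex I was higher by 1.61 (SE 0.112, adjusted p = 1.11e-07) and Uqcrq of complex III by 1.304 (SE 0.112, adjusted p = 8.96e-07), while Cox7a2l, an assembly factor of supercomplexes, was lower at −0.52. Fatty acid oxidation had 10 of 16 genes higher and 0 lower (11 and 0 adjusted over the list alone), median 0.49 (camera adjusted p = 0.00146; adjusted p = 0.759 with an estimated correlation), with Cpt2 and Cpt1a, which carry fatty acids into mitochondria, higher by 2.18 (SE 0.176) and 1.498 (SE 0.129). The TCA cycle had 12 of 18 higher and 1 lower (12 and 1 adjusted over the list alone), median 0.50 (camera adjusted p = 0.00503; adjusted p = 0.759 with an estimated correlation). Suclg1 was higher there by 1.16 (SE 0.138), as was Mdh1, which the list holds though it encodes the cytosolic malate dehydrogenase, by 1.12 (SE 0.150). Idh2 stood at −1.17 but at 1.09 with 9 classes. The pentose phosphate pathway had 5 of 7 higher and 1 lower (6 and 1 adjusted over the list alone), median 0.88 (camera adjusted p = 0.0254; adjusted p = 0.759 with an estimated correlation), with G6pdx, its entry enzyme, higher by 1.34 (SE 0.174) and Taldo1 by 1.28 (SE 0.120), and Rpia lower at −0.59. The calls of the TCA cycle, the pentose phosphate pathway and fatty acid oxidation were also lost with 9 classes. Mitochondrially encoded genes were not called in luteal cells (median 0.11, camera adjusted p = 0.246), and their share of UMIs, 3.3252% and 4.9735%, lay under the 3.7996% and 5.1878% of granulosa cells.

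Antioxidant genes were higher in luteal cells too, 15 of 23 against 3 lower (15 and 3 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.00263; adjusted p = 0.759 with an estimated correlation). Gpx3, a secreted glutathione peroxidase, was higher by 4.23 (SE 0.149) and Srxn1, which restores peroxiredoxins, by 2.35 (SE 0.170). Nqo1 had 3 counts in luteal cells, a ratio to the mean of the other classes of 0.114 (95% counting interval 0.0236 to 0.334). Gpx8 was at −1.25 and turned to 1.01 with 9 classes. Genes known to respond to tissue dissociation, mostly immediate early and heat shock genes, were lower in luteal cells, with 0 of 20 higher and 14 lower (0 and 14 adjusted over the list alone), median −0.74 (camera adjusted p = 0.00503; adjusted p = 0.759 with an estimated correlation), and fry in place of camera ended that call. They were higher in surface epithelial cells, 15 of 20 against 2 lower (15 and 3 adjusted over the list alone), median 1.17 (camera adjusted p = 0.00180; adjusted p = 0.759 with an estimated correlation). Atf3 was higher there by 3.65 (SE 0.161) and Dusp1 by 2.29 (SE 0.163), with Atf3 at 2417 and 3098 CPM. The heat shock genes Hspa8 and Dnajb1 were lower, at −0.56 and −0.58, and Dnajb1 stood at 0.01 with 9 classes, still under the median of all genes of 0.29.

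Stromal fibroblasts and surface epithelial cells were lower in oxidative phosphorylation than the mean of the other classes. That mean includes the high luteal level, so these values in part mirror the luteal result and are not separate from it. In stromal fibroblasts 33 of 78 nuclear genes were lower and 2 higher (33 and 2 adjusted over the list alone), median −0.27 (camera adjusted p = 2.20e-05; adjusted p = 0.759 with an estimated correlation). In surface epithelial cells 40 were lower and 7 higher (40 and 7 adjusted over the list alone), median −0.35 (camera adjusted p = 8.06e-04; adjusted p = 0.759 with an estimated correlation), and both calls were lost with 9 classes, where the surface epithelial median of 0.09 still lay under the 0.29 of all genes. Stromal fibroblasts were also lower in 8 of 13 mitochondrially encoded genes (8 adjusted over the list alone), median −0.34, with mt-Nd2 at −0.82 (SE 0.120) and mt-Co1 at −0.79 (SE 0.111), and in 10 of 16 fatty acid oxidation genes against 1 higher (10 and 1 adjusted over the list alone), median −0.50. Both lists had a camera adjusted p of 0.0175 (adjusted p = 0.759 with an estimated correlation), and both calls were also lost with a finer clustering, with each library clustered by itself, with equal cell numbers, with 9 classes and with the library 1 cluster counted as luteal. Over 20 tested alternatives the mitochondrially encoded call held in 13 and that of fatty acid oxidation in 12. In surface epithelial cells the fatty acid oxidation list had a median of 0.01 with a test pointing down, and the angiogenic ligands a median of −0.23 with a test pointing up, neither called.

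Genes of cell senescence and of its secreted factors were higher in stromal fibroblasts and lower in granulosa cells. In stromal fibroblasts 16 of 24 measured were higher and 5 lower (16 and 5 adjusted over the list alone), median 1.83 (camera adjusted p = 0.00339; adjusted p = 0.759 with an estimated correlation), a call also lost with equal cell numbers per class. The members that were higher there included matrix and growth factor binding proteins that fibroblasts are known to make, such as Igfbp7 (7.69, SE 0.279), Mmp2 (5.24, SE 0.243) and Igfbp4 (5.26, SE 0.156), and the chemokine Ccl2 (5.99, SE 0.542), whereas the cell cycle inhibitor Cdkn1a was lower, at −0.96 (SE 0.238). These 5 genes in this class fall outside the naming rule and were chosen after their values were seen. Surface epithelial cells had a like median of 1.86, with 13 higher and 4 lower (13 and 4 adjusted over the list alone). The list was not called there (camera adjusted p = 0.0898). In granulosa cells 18 were lower and 1 higher (18 and 1 adjusted over the list alone), median −3.31 (camera adjusted p = 2.96e-05; adjusted p = 0.759 with an estimated correlation). Ccl7, a chemokine, had no count in granulosa cells of either library and was at least 260-fold lower than the mean of the other classes, against a floor of 3 counts over the class. Ccl2 stood at 0 and 0.128 CPM. The list's median was the same with the genes without counts set at their bound. Among the 12 angiogenic ligands, called in no class, granulosa cells were higher in Pdgfb (1.17, SE 0.174) and Pdgfc (1.07, SE 0.197), which encode platelet-derived growth factors, and lower in Angpt1 (−3.62, SE 0.396) and Fgf2 (−3.38, SE 0.582). The calls of Angpt1, Fgf2 and both chemokines were lost with 9 classes.

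**Figure D4:**
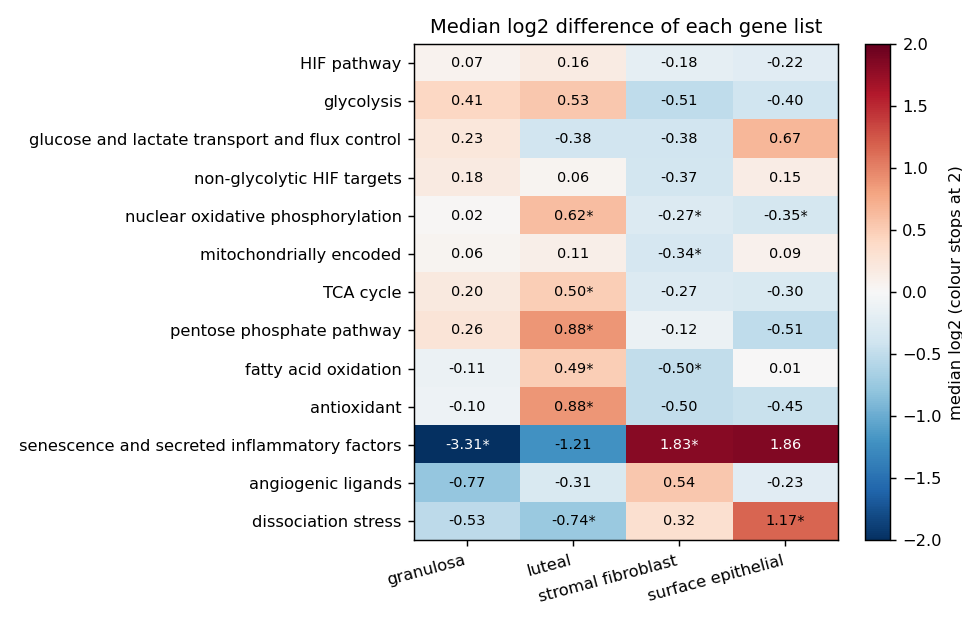
Median log2 difference of each gene list (rows) in each tested class (columns) against the mean of the other classes, with colour that stops at 2 and an asterisk where camera's adjusted p was under 0.05 at its preset correlation. Luteal cells stood at 0.62 for oxidative phosphorylation, and the glycolysis list at 0.41, 0.53, −0.51 and −0.40 carried no asterisk.

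Cells in which Hif1a was detected were set against cells of the same class and library in which it was not, since the series links HIF1A to glycolysis. At 2000 UMIs per cell, 360 cells of library 1 and 1499 of library 2 had a Hif1a UMI, and as many undetected cells were drawn. Of 10593 genes, 9 were higher and 26 lower in detected cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8 and 26 of them with the same sign in both libraries. Those higher in detected cells included Inhbb, an inhibin subunit, by 0.54 (SE 0.0796, adjusted p = 1.74e-08), Nap1l5 by 0.46 (SE 0.0779), Hsd17b1, which makes estradiol, by 0.30 (SE 0.0620), Gja1, the gap junction protein connexin 43, by 0.20 (SE 0.0452) and Dab2 by 0.48 (SE 0.114). Inhbb, Nap1l5 and Hsd17b1 were also among the 10 leading genes of granulosa cluster 6, where Hif1a was higher too. Cells were matched by class and not by cluster, so these genes may reflect the make-up of the clusters. Xcl1, a lymphocyte chemokine (3.25, SE 0.512), Lyz2, the lysozyme of macrophages (2.80), and Col1a1 (0.54, SE 0.140) were also higher, and the 1 other gene called had opposite signs in the libraries. In libraries 1 and 2 only 2 and 9 NK cells had a Hif1a UMI, and 1 and 5 macrophage- or monocyte-like cells. The calls of Xcl1, an NK cell marker here, and of Lyz2 may therefore rest on few cells. The 10 lower genes with the largest differences were Ccl21a, a chemokine of lymphatic vessels (−1.98, SE 0.219), Rgs5 of pericytes (−2.44, SE 0.341), Acta2 (−0.96) and Myl9 (−0.98, SE 0.234) of smooth muscle, the antigen presentation genes Cd74 (−0.61, SE 0.132) and H2-Aa (−1.08, with 0 and 16.7 CPM in detected cells against 6.94 and 32.7), Ccl4 (−2.53, with 0 and 8.01 CPM against 1.39 and 45.7), Scx (−1.32), Nrgn (−1.03) and Crip1 (−0.56, SE 0.0763). Acta2 was at 106 CPM on both sides in library 1.

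Glycolysis genes did not pass the test between detected and undetected cells. None of the 19 measured genes was called over all genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and adjusted over the list alone 5 were higher and 1 lower. The list's median was 0.15 (0.02 to 0.26 over the alternatives), with 0.16 in library 1 and 0.13 in library 2, and camera gave an unadjusted p of 0.0338 and an adjusted p of 0.220 (0.999 with an estimated correlation). Aldoa stood at 0.23 (SE 0.0630, adjusted p = 0.0651), Pgk1 at 0.26 (SE 0.0986), Ldha at 0.21 (SE 0.0736), Pkm at 0.19 (SE 0.0772) and Ldhb at −0.19 (SE 0.0667). The carriers Slc2a1 and Slc16a1 stood at 0.47 (SE 0.233) and 0.36 (SE 0.144), and Epas1 at 0.23 (SE 0.134). The dissociation genes were lower in detected cells as a list, with 0 of 20 higher and 6 lower (0 and 14 adjusted over the list alone), median −0.20 (camera adjusted p = 0.00739; adjusted p = 0.999 with an estimated correlation). For the TCA cycle the median of −0.02 and the mean of 0.02 differed in sign, with no call.

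The same split was made on each of 100 other genes seen in a like share of cells, to show what any splitting gene gives. They gave a median of 18 called genes (0 to 631), and 34 of the 100 gave at least the 35 of Hif1a. Their glycolysis medians ran from −0.26 to 0.31, with 9 of 100 at or above that of Hif1a, and 80 had a dissociation median at or above −0.20. Without matching by class 933 genes were called, with cells matched by cluster 4, and with the 6% of cells of highest doublet score removed 2. DESeq2 called 0 genes, with 22 at an unadjusted p under 0.05 against 655 by edgeR's quasi-likelihood test, and edgeR without the library in the model also called 0, with 85 unadjusted. Lyz2, Rgs5, Acta2, Col1a1, Ccl4, Scx, H2-Aa and Myl9 changed sign in at least 1 alternative, so no direction rests on them. The others kept their sign, but over 12 alternatives the calls of Nap1l5, Hsd17b1 and Crip1 held in 4 and those of Gja1, Dab2, Cd74 and Nrgn in 3, with values as near to 0 as 0.15, 0.06, −0.01, 0.02, 0.08, −0.11 and −0.11. The call of Inhbb held in 7 of 12 (lowest value 0.27), that of Ccl21a in 7 of 10 and that of Xcl1 in 5 of 11.

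**Figure D5:**
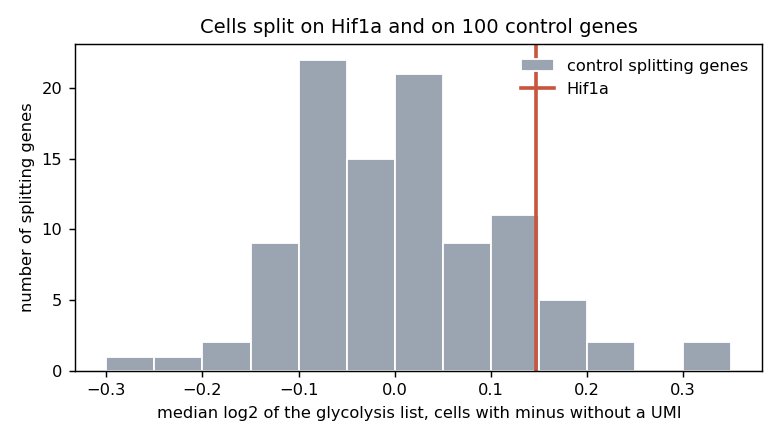
Median log2 difference of the glycolysis list between cells with and without a UMI of the splitting gene, as a histogram over 100 control genes (number of genes on the vertical axis), with a line for Hif1a. The controls ran from −0.26 to 0.31 and Hif1a stood at 0.15.

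Set side by side, the libraries differed at least 3-fold in the same direction in all 4 tested classes for genes that included mt-Atp8, a mitochondrially encoded subunit of ATP synthase (median 5.49-fold), and Gm11808, a predicted gene (3.94-fold), each at 100 CPM or more in at least 1 library and each higher in library 1. In 3 classes Snhg9 (5.98-fold), AY036118 (4.24-fold), the mitochondrial leucyl-tRNA synthetase Lars2 (4.24-fold) and Polr2l, a shared subunit of the RNA polymerases, were higher in library 1. Gm11808 may share reads with other genes, and AY036118, Gm42418 and Lars2 lie in or resemble ribosomal RNA repeats, so their values are uncertain. Higher in library 2 in 2 classes were Inhba, an activin subunit, Tenm4 and Igfbp5. In luteal cells Inhba stood at 50.9 CPM in library 1 and 221 in library 2. No group separates the libraries, and no test was made.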

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

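The tests of droplets with mixed cells and of a shift of library 1 in this part were chosen only after the result was seen. EGFP, a sequence added to the reference that no comparison used, was seen as 4 UMIs in library 1 and 17 UMIs in library 2, above the limit of 3 counts that a count of 0 allows, with at most 1 UMI in any cell. In library 2 granulosa cells held 9 of them, surface epithelial cells 3, and luteal and stromal fibroblast cells 2 each.

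A cluster outside every class held 293 cells of library 1 and 2 of library 2, which singled it out as a signal in data that the comparisons left aside. Its cells had 8 of 10 luteal markers detected, were led by Edn2, the endothelin that makes the follicle wall contract, and had a median of 18839 UMIs. The cluster was kept out of the luteal class because the theca marker Mgarp, and no luteal marker, was among its 10 leading genes. Its glycolysis list stood above that of luteal cells of the same library by a median of 0.58 on the log2 scale (percentile 100 among 10000 random lists, with 5 CPM added to each level for this and the other lists of the cluster), with Eno1 3.77-fold (95% counting interval 3.27 to 4.35), Pfkl 3.24-fold (2.31 to 4.55) and Ldha 2.52-fold (2.31 to 2.76). HIF targets outside glycolysis lay above luteal cells too, by a median of 0.45 (percentile 99.92), with 6 of 21 at least 2-fold higher and 2 lower, but less above granulosa cells, at 0.25 (percentile 96.41). Among them Bnip3 and Ndrg1 stood 3.34-fold and 2.89-fold above luteal cells and Hif1a 1.64-fold (1.46 to 1.84), with Hif1a 1.12-fold above granulosa cells (1.06 to 1.18), whereas Vegfa and Adm stood at 0.678 and 0.244 of the luteal level. Oxidative phosphorylation, the TCA cycle and fatty acid oxidation lay below luteal cells, by −0.44, −0.38 and −0.33, at percentiles of 0, 0 and 0.01 of random lists, but not below granulosa cells, at 0.01, −0.04 and 0.06 (percentiles 62.2, 31.28 and 55.72).

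Luteal and granulosa cells caught in the same droplet would give levels between those of the 2 types, but 11 of 15 glycolysis genes lay above both beyond their counting intervals, which argues against such droplets as the whole source. A shift shared by all cells of library 1 would cancel in these comparisons, which were made within that library. Values between the libraries therefore do not bear on them. Within the 4 tested classes the median glycolysis gene of library 1 over library 2 ran from −0.2188 (stromal fibroblasts) to 0.0678 (surface epithelial cells) on the log2 scale. A candidate explanation that remains open is cells shortly after the ovulatory LH surge. Of 20 genes known to be induced by the surge, the 12 measured against luteal cells lay above them at percentile 100 (4 at least 2-fold higher and 0 lower with 5 CPM added) and the 10 measured against granulosa cells at 99.98 (5 higher, 3 lower), with Runx1 at 524 CPM against 98.5 and 87.9 and Tnfaip6 at 79.6 against 13.1 and 17.8, though Rgs2, at 138 CPM against 193 and 622, was lower than in both, Ctsl (1434 against 3140) and Nrip1 (145 against 375) were lower than in granulosa cells, and Pgr, Ptx3 and Has2 were near 1 CPM or under it. The list was written before its test but after the leading genes of the cluster had been seen, and with nearly all cells in library 1 a feature of that library alone stays open.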

How the results depend on the processing

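The removal of high doublet scores, the 9 classes, matching by cluster and the luteal class with the library 1 cluster were tests chosen only after the result was seen. Among the alternatives run, Hif1a kept its direction in all 4 classes, with a range of 0.73 to 0.87 in granulosa cells. Of the 19 alternatives with a test, it kept its side of the threshold in 19 in granulosa and 18 in luteal cells. In stromal fibroblasts it did so in 15 and in surface epithelial cells in 17. The glycolysis list kept both in 19, 16, 18 and 20 of 20 tested alternatives in granulosa, luteal, stromal and surface epithelial cells. The next counts also hold values of each library by itself, which have no test. Those counted as kept with the same sign and within the standard deviation of the 2 libraries' values from the main value, a loose limit. So counted, other called lists were kept in 247 of 286, named genes by class in 1763 of 1909, and genes named from the split in 93 of 241. Of 120 class shares 102 stayed within the 95% interval of the main share. The 2 libraries and the small luteal and stromal classes of library 1 limit every test, and the split counts moved most. The cause of the changes that follow was not tested.

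Cells called by UMI rank gave Hif1a in luteal cells 0.31 (adjusted p = 0.0350, range over all alternatives 0.0350 to 0.580). The stromal call of Hif1a was lost with no replicate block, that is without the library in the model (−0.45, adjusted p = 0.0661), with equal cell numbers (−0.52, 0.0595), 9 classes (−0.34, 0.147) and the library 1 cluster as luteal (−0.53, 0.0598), and the surface epithelial call with equal cell numbers (−0.40, 0.115) and 9 classes (−0.41, 0.0560), by edgeR. The block pairs the classes of each library, which come from the same suspension.

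The glycolysis list passed with high doublet scores removed in granulosa (0.45), luteal (0.44) and stromal cells (−0.55), without a low-count filter in luteal (0.37) and stromal cells (−0.61), and in luteal cells with 2000 UMIs as minimum (0.56) or the library 1 cluster added (0.78), none of them with an estimated correlation (adjusted p of 0.565 or more). With a library left out its median ran from 0.24 to 0.64 in luteal and from −0.43 to −0.39 in surface epithelial cells. With 9 classes the oxidative phosphorylation median of surface epithelial cells stood at 0.0864, under the median of all genes of 0.29.

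Shares of granulosa cells in libraries 1 and 2 were 52.6% and 55.1% with 2000 UMIs as minimum, 57.7% and 61.5% with cells called by UMI rank and 51.3% and 56.4% with high doublet scores removed. Calling by rank also gave luteal shares of 3.96% and 6.57%, stromal shares of 4.12% and 5.24% and a surface epithelial share of 17.7% in library 2, and no T or NK cell class. With high doublet scores removed macrophage- or monocyte-like cells made up 0.257% of library 1. Clustered without library 2, library 1 had 0 endothelial, theca, NK and macrophage cells by name, 2.24% T cells and 7.09% stromal fibroblasts.

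The split on Hif1a called 3 genes at 1000 UMIs, 933 without matching, 6 at a mitochondrial limit of 15%, 16 with Scrublet calls kept, 2 with high doublet scores removed, 4 matched by cluster, 0 by DESeq2 and 0 with no replicate block. Keeping Scrublet calls restored only 5 barcodes. Settings that change the cells, their matching or the depth also change the random draw of cells. The spread between draws was not measured, so these changes cannot be credited to the setting itself. Without thinning its glycolysis median was 0.26 (camera adjusted p = 0.0207, range 0.0207 to 0.972; adjusted p = 0.700 with an estimated correlation). The main median of 0.15 fell to 0.03 at 1000 UMIs, 0.05 at 4000, 0.06 with Scrublet calls kept, 0.07 with high doublet scores removed and 0.02 matched by cluster.

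Signs turned with 9 classes for Pfkp in granulosa (−0.11) and luteal cells (−0.45), and in luteal cells for Ldhb (0.50), Slc16a1 (0.0689), Idh2 (1.09) and Gpx8 (1.01), for Edn1 in stromal (0.30) and Dnajb1 in surface epithelial cells (0.0104). That fit raised the median of all genes to 0.33 in luteal, 0.26 in stromal and 0.29 in surface epithelial cells, so Slc16a1 and Dnajb1 still lay under it and Edn1 near it. Slc16a3 in granulosa cells turned with equal cell numbers (−0.86) and with the library 1 cluster as luteal (−0.027). In the split, thinning to 1000 UMIs turned Col1a1 (−0.35), Myl9 (0.69) and Acta2 (0.21), thinning to 4000 turned Lyz2 (−2.25), Rgs5 (0.96), H2-Aa (0.30) and Acta2 (0.15), and no thinning turned Lyz2 (−1.62), Rgs5 (0.53) and Acta2 (0.57). Without matching Lyz2 (−1.25) and Col1a1 (−0.73) turned, at a mitochondrial limit of 15% Lyz2 (−0.47) and Ccl4 (1.83), with Scrublet calls kept Lyz2 (−1.54), Rgs5 (2.35), Scx (0.32) and Acta2 (0.12), and with high doublet scores removed Acta2 (0.0168).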

Other observations

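The tests by granulosa cluster, those of depth and of HIF activity and the shares of control genes in this part were chosen only after the result was seen, as was the comparison over 9 classes. With the smaller classes included, blood endothelial cells joined granulosa cells as the classes with more Hif1a than the mean of the other classes, by 0.49 on the log2 scale (SE 0.162, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0337) at 231 and 242 CPM. The median of all genes in that fit was 0.29 in endothelial cells, so most of the 0.49 is a shift that the typical gene shares. Theca and T cells stood at −0.03 and 0.04, NK cells at −0.38 and macrophages or monocytes at −0.28, with none of these passing and all-gene medians of 0.25, −0.43, −0.65 and 0.10. The Hif1a values of T and NK cells lay above those medians, but that difference was not tested. They rest on 12 and 43 Hif1a counts in T cells and 8 and 24 in NK cells. The glycolysis list made up 0.393% and 0.400% of theca UMIs, 0.296% and 0.387% of endothelial UMIs, 0.292% and 0.297% of T cell UMIs, 0.217% and 0.230% of NK cell UMIs and 0.497% and 0.304% of macrophage or monocyte UMIs (10 and 30 cells), where the libraries disagreed.

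Granulosa cells were not uniform. In cluster 6, with 118 cells of library 1 and 230 of library 2 and led by Cox4i2 and Inhbb, 13 of 20 glycolysis genes were higher than in the other granulosa clusters and 1 lower (14 and 1 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 4.66e-06; adjusted p = 0.522 with an estimated correlation). Ldha was higher by 1.68 (SE 0.113), Eno1 by 1.605 (SE 0.139) and Hif1a by 0.59 (SE 0.0961), and Ldhb was lower (−0.50, SE 0.0890). Nuclear genes of oxidative phosphorylation had a median of 0.52 and mitochondrially encoded genes one of −0.13, at 3.298% and 4.804% of UMIs against 3.7996% and 5.1878% over all granulosa cells, and dissociation genes were lower in 16 of 20. Cluster 12, led by matrix genes such as Itih5 and Col11a1, went the other way, with 13 glycolysis genes lower and 1 higher (13 and 1 adjusted over the list alone; camera adjusted p = 3.89e-05; adjusted p = 0.522 with an estimated correlation), median −0.68, and Hif1a at −0.66 (SE 0.114). Cluster 8 had 12 of 13 mitochondrially encoded genes higher, median 0.39 (camera adjusted p = 1.00e-05; adjusted p = 0.522 with an estimated correlation).

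With every cell thinned to 5000 UMIs (leaving out 16 and 52 shallower granulosa cells), the glycolysis median of cluster 6 was 0.961. The list still passed (camera adjusted p = 7.22e-08, and 0.257 with an estimated correlation). A larger weight of deep cells in the sums is thus argued against. Thinning keeps the expected share of each gene within a cell, so it cannot tell whether RNA-rich cells hold more glycolysis UMIs. Depth in that sense stays open. The deeper clusters 2 and 9 (median 29277 and 33112 UMIs against 21554) held smaller glycolysis shares, 0.644% and 0.511%, and 0.558% and 0.445%. Cluster 4, at a median of 23155.5 UMIs, held 0.415% and 0.4765%. The shallower clusters 1, 7, 8, 12 and 14 also held smaller shares, from 0.244% to 0.457% in library 1 and from 0.287% to 0.516% in library 2. Free RNA is argued against: glycolysis genes made up 0.762% and 0.776% of the UMIs of cluster 6 against 0.456% and 0.441% of free RNA, a ratio of at least 1.671 in both libraries. HIF activity stays open. Hif1a was higher in the cluster, and the HIF targets outside glycolysis, with a median of 0.19, passed camera at the preset correlation (adjusted p = 0.0237) and not with an estimated correlation (adjusted p = 0.522). The glycolysis list of the cluster has the same tied value of 0.522, so that check does not tell the lists apart. No biological explanation from the design was tested, since the labels give no follicle stage.

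A split of cells on Hif1a could be expected to mark cells with more HIF activity. The 35 called genes are no more than many other genes give, since 34 of 100 control genes called as many, and 9 of 100 control genes gave as high a glycolysis median. No difference in glycolysis beyond that of a like splitting gene was therefore seen at 2000 UMIs per cell, where a Hif1a UMI is missed in most cells that hold one without thinning (34.4% against 83.4% of cells in library 1). With cells matched by cluster in place of class, 4 genes were called and the glycolysis median was 0.02. A difference in the make-up of clusters within a class therefore stays open. No biological explanation was tested here, since both libraries belong to the same group.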
